A study of Mus musculus with 236 samples.

How the data were processed

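The series holds 236 mouse samples. Of these, 218 have RNA-seq count tables and 12 have SLAM-seq tables, and the 6 ATAC-seq samples, deposited without a processed file, were not analysed here. The deposited RNA-seq values are counts of reads for 20632 gene symbols, whole numbers whose totals differ between libraries. Per the submitters' processing notes the tools were BWA 0.7.12, SAMtools 1.3.1, TopHat2 2.1.1, HTSeq 0.6.1 and TopHat with the mm10 build, and GRCm38 is also named for the libraries of Rag2-/- mice. The SLAM-seq tables list 22552 gene IDs, of which 22496 (99.75%) were matched to a symbol. They hold deposited counts of all reads and of reads with T-to-C conversions, which mark newly made RNA. For these the notes name bedtools, cutadapt and Trim Galore 0.3.7 with mm10 and GRCm38. A further column of CPM values, made by the authors in the SLAM-seq tables, was not used here. The order of the tools, counting options, strand setting and annotation were not stated. Class I heavy chains, guanylate-binding proteins and Ifit genes have close copies, so reads shared between copies, or with genes on the other strand, leave their values uncertain.

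Libraries were grouped by model, material and treatment as the labels give them, in 54 groups. The 3 technical libraries of each Rag2-/- mouse were summed. Groups taken 7 or 9 days after T cell transfer and interferon-treated NSG-derived cells were in the fits but in no comparison of the results. Replicate libraries differed by more than counting error, the lowest chi-square per degree of freedom of a pair being 1.856. Intervals and floors cover counting error only. A fold against a group without a read was computed against 3 counts over the group, and 1 to 3 counts are given as a ratio with its exact (Clopper-Pearson) 95% interval.

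Each library series was fitted as 1 model with all its groups in edgeR 4.0.16 (R 4.3.3), with TMM normalization and filterByExpr by group (minimum count 10, minimum total 15). The quasi-likelihood test was used with Benjamini-Hochberg adjusted p under 0.05 in each comparison. Braf/Pten cells in vitro had the title code as a batch term. A difference of responses was tested as a contrast of 2 effects. The SE is the log2 fold change divided by the square root of the F statistic. CPM use TMM-scaled library sizes, and log2 CPM a prior count of 2. SLAM-seq tests used converted reads, with library sizes and TMM factors from all reads. The 28 gene lists hold 320 entries, 308 of them in the count tables. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, and their members were also adjusted over the list alone. Not every list is printed for every comparison.

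The named genes are, in each comparison, the 8 largest positive and 8 largest negative log2 fold changes among genes past the threshold with an average log2 CPM of at least 3 (0 in converted reads). Their groups must not overlap, except in dendritic and T cells and in differences of responses. Predicted and unnamed genes are left out. To these come up to 4 members of each list with the smallest adjusted p, or 2 with the highest average where none passed. The text names a part of them, and Lyz2 and C1qb in sorted T cells and Lyz2 in CD103+ cells were added after their values were seen.

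Comparisons, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were RLE normalization, no filter on low counts, DESeq2 1.42.0, a fit of the compared groups alone and leaving out each library of groups of 2 to 5. Where they apply, others were title codes taken singly or without a batch term, no libraries far below the median depth, 1 technical library per mouse, replicate numbers as blocks (coding set later), and all reads in SLAM-seq. Later additions were leaving out resistant T cell libraries 7 and 9 and scaling SLAM-seq by converted reads. Other splits of the libraries were counted, all of them where there were up to 100 and otherwise 40 drawn, or 21 for a difference of responses (seed 1). Groups of 4 to 10 libraries were searched for a library apart with Dixon's test. Correlations were tested with 100000 permutations, 2-sided (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). The fits were tested on simulated counts with 200 changed genes per comparison, of which 28 to 100 percent of those changed 4-fold and 4 to 90 percent of those changed 2-fold were called.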

Results

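RNA was measured in 3 mouse tumor models made resistant to targeted drugs. The material was cells grown in culture, whole tumors and cell types sorted from tumors. The study's title names acquired resistance to targeted therapy and cross-resistance to immunotherapy as its subject. Tumor cells that had not met the drug are called naive here (the labels write NTT). Cells that had become resistant to it are called resistant (RTT). The Braf/Pten model is a melanoma line (YUMM1.7 in one part of the labels) and the Braf model a second Braf-driven line. Both were treated with the BRAF inhibitor dabrafenib. CT26, a colon carcinoma line, was treated with the MEK inhibitor trametinib.

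Cultured cells gave 21 Braf/Pten, 18 Braf and 12 CT26 libraries, and whole tumors 10, 9 and 9. Sorted cells gave 36 libraries of CD11c+ CD103+ dendritic cells and 19 of CD45+ leukocytes. There were 21 of CD3+ CD8+ T cells taken 72 h after adoptive T cell transfer (ACT), and 16 and 11 of GFP+ Braf/Pten tumor cells. A further 36 libraries of tumor cells came from Rag2-deficient mice, which lack mature T and B cells. They were technical repeats, 3 per mouse, and were summed to 12 mice. Newly made RNA, labelled for 90 min with 4-thiouridine, was read in 12 SLAM-seq libraries. The median total count per library was 14246098 in Braf/Pten, 5089754 in Braf and 5316692 in CT26 cells. Whole tumors had 12665437, 4222313 and 3232258, and sorted dendritic cells, leukocytes, T cells and the GFP+ sets 1473856, 2600002, 2246857, 2622225 and 4555443. Fold changes are edgeR estimates with Benjamini-Hochberg adjusted p, log2 values carry the SE, and levels are given as CPM. Gene lists were fixed before the data were examined and tested with camera. Where a list's call was lost with the correlation between its genes (r) estimated, that p is given beside it. List counts name 1 direction where no member was called in the other. Counts adjusted over the list alone are given where they differ. Except for the Rag2-deficient mice, the labels do not say whether libraries of a group came from separate cultures or animals. The p-values therefore measure only the spread between these libraries.

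Resistant Braf/Pten cells, kept in 100 nM dabrafenib, were first compared with naive cells in medium without it. Among the genes with the largest rises were Lox (372-fold higher, adjusted p = 4e-10) and Tagln (808-fold higher, adjusted p = 2.8e-17), a collagen cross-linking enzyme and an actin-binding protein. The matrix proteins Thbs1 (21.2-fold higher, adjusted p = 1.3e-07) and Ltbp2 (394-fold higher, adjusted p = 3.8e-15) rose too. Interferon-stimulated genes fell together. The antiviral effector Rsad2 was 62.9-fold lower and the T cell attractant Cxcl10 16.7-fold lower (adjusted p = 8.8e-09 and 4.6e-08). The transcription factor Stat1 was 4.27-fold lower. Every antiviral gene was lower (19 of 19 lower, camera adjusted p = 4.8e-11 and adjusted p = 0.151 with r estimated). The list median was -3.55 on the log2 scale. The interferon-gamma response list was lower (1 higher and 11 lower of 16, camera adjusted p = 6.6e-06 and adjusted p = 0.151 with r estimated). So was the MHC class I list (1 higher and 9 lower of 13, 1 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.00048 and adjusted p = 0.244 with r estimated). H2-K1, a class I heavy chain, stood at -1.30 ± 0.13. Transcripts that follow ERK activity were lower (14 of 18 lower, camera adjusted p = 4.8e-06 and adjusted p = 0.104 with r estimated). Among them was the feedback phosphatase Dusp6 (4.31-fold lower, adjusted p = 1e-09). All 18 cell cycle genes were called higher, for example Cdc20 (1.74 ± 0.25) and Ccna2 (1.54 ± 0.18), with camera adjusted p = 6.6e-06 and adjusted p = 0.287 with r estimated. Cytokines split, with Csf1, a macrophage growth factor, 3.55-fold higher and Ccl2, a monocyte attractant, 6.95-fold lower. Their list was not called (4 higher and 8 lower of 15, 5 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.312). In all, 6764 of 12039 genes (3567 higher and 3197 lower) were called. The libraries carried 2 title codes, which the fit held as a batch term. Under the code ending in LH1 alone 7017 genes were called and under the one ending in LH2 4597. The antiviral median was -2.44 and -5.14 under LH1 and LH2, with 19 of 19 genes lower in each. Of the cell cycle genes, under LH1 18 were higher with a median of 1.89, and under LH2 5 with a median of 0.29.

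Acute treatment of naive Braf/Pten cells with 100 nM dabrafenib for 48 h lowered ERK target genes and cell cycle genes. The AP-1 member Fosl1 was 50.3-fold lower, Etv4 55.7-fold lower and Myc 21.5-fold lower (adjusted p = 6.6e-13, 9.1e-10 and 3.3e-10). Their list fell (1 higher and 17 lower of 18, camera adjusted p = 9.2e-11). Cell cycle genes fell (18 of 18 lower, camera adjusted p = 3.7e-09), such as Ccnb1 at -2.52 ± 0.32. So did antiviral (19 of 19 lower, camera adjusted p = 3.2e-10), MHC class I (12 of 13 lower, camera adjusted p = 3.1e-06) and interferon-gamma response genes (13 of 16 lower, 15 lower adjusted over the list alone, camera adjusted p = 2.5e-07). These 4 lists had adjusted p from 0.127 to 0.18 with r estimated. The checkpoint ligand Cd274 was 21.4-fold lower (adjusted p = 6e-07). The largest rises included Lox (8.08 ± 0.59), Ccdc80 (6.93 ± 0.41) and Mfap4 (7.11 ± 0.33). Cxcl12, a chemokine of stromal cells, was 5.23-fold higher. The fit called 6202 of 12039 genes (3004 higher and 3198 lower). These libraries share their naive controls with the resistant comparison.

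Interferon (10 ng/ml, 24 h, type not named) was then added to naive cells. The guanylate-binding proteins Gbp4 and Gbp2 rose, Gbp4 77-fold higher (adjusted p = 2.2e-09) and Gbp2 54.1-fold higher. So did antigen processing, with the immunoproteasome subunit Psmb9 at 5.96 ± 0.25 and H2-K1 at 3.29 ± 0.17. All 13 class I genes were called higher (camera adjusted p = 1.3e-36), as were 16 of 16 interferon-gamma response genes and 19 of 19 antiviral genes (camera adjusted p = 3.1e-31 and adjusted p = 4.5e-18). Among those that fell most were Ogn (-2.30 ± 0.47) and Glt8d2 (-2.26 ± 0.22). In all, 1194 of 12039 genes (721 higher and 473 lower) changed. There were 701 from these groups alone, 734 under 1 title code and 508 without naive interferon library 1. In resistant cells on dabrafenib the same dose raised Gbp4 797-fold, Gbp2 355-fold and the GTPase Igtp 161-fold (adjusted p = 6.5e-12, 3.5e-12 and 5.6e-12). H2-K1 reached 961 ± 35.5 against 114 ± 71.1 CPM (SD, n = 3 and 6). Class I genes rose (13 of 13 higher, camera adjusted p = 2.5e-54), as did interferon-gamma response genes (14 of 16 higher, 15 higher adjusted over the list alone, camera adjusted p = 3.6e-49) and antiviral genes (12 of 19 higher, 17 higher adjusted over the list alone, camera adjusted p = 1.4e-26). Here 601 of 12039 genes (394 higher and 207 lower) changed, or 398, 387 and 372 without resistant interferon libraries 1, 2 and 3 in turn and 1001 without resistant library 4. Testing the difference itself, resistant minus naive, it was positive for 37 genes and negative for 38. The interferon-gamma response list rose more in resistant cells (9 higher and 1 lower of 16, 12 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.4e-13). Examples are Gbp7 (3.03 ± 0.38), Gbp5 (3.70 ± 0.53) and Iigp1 (3.50 ± 0.61) on the log2 scale. Gbp7 stood at 409 ± 65.6 against 394 ± 123 CPM (SD, n = 3 each) with interferon and 18.8 ± 17.1 against 127 ± 91.7 CPM (SD, n = 6 each) without, resistant against naive. No antiviral gene differed in response over all genes tested (0 of 19 by edgeR, 1 lower adjusted over the list alone). For this difference DESeq2 called 246 genes where edgeR called 75. By edgeR it was 35 under 1 title code and 48, 49 and 45 without resistant interferon libraries 1, 2 and 3 in turn, 127 without naive interferon library 3 and 180 without naive library 4.

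In whole Braf/Pten tumors, 3 days of dabrafenib (30 mg/kg) lowered proliferation genes and raised markers of endothelial and immune cells. Cell cycle genes fell (18 of 18 lower, camera adjusted p = 1.4e-17). The proliferation marker Mki67 stood at 74.5 ± 1.16 against 434 ± 65.5 CPM (SD, n = 3 each). ERK target genes were lower (8 of 18 lower, 1 higher and 12 lower adjusted over the list alone, camera adjusted p = 2e-05), among them Fosl1 (8.77-fold lower, adjusted p = 0.00192) and Ccnd1 (4.24-fold lower). These lists had adjusted p from 0.287 to 0.585 with r estimated. Endothelial (4 of 7 higher, camera adjusted p = 0.0392), macrophage (5 of 16 higher, 7 higher adjusted over the list alone, camera adjusted p = 0.00205) and T cell markers (3 of 11 higher, 7 higher adjusted over the list alone, camera adjusted p = 0.00448) rose, with adjusted p from 0.402 to 0.585 with r estimated. Vwf, a clotting factor of vessel walls, was 4.07-fold higher and the T cell kinase Lck stood at 2.18 ± 0.50. MHC class II genes passed only over their own list (0 of 7 called, 7 higher adjusted over the list alone, camera adjusted p = 0.0378 and adjusted p = 0.585 with r estimated). H2-Aa was at 2939 ± 454 against 910 ± 138 CPM (SD, n = 3 each). No antiviral gene was called (0 of 19 called, camera adjusted p = 0.0392 and adjusted p = 0.652 with r estimated). The fit called 2577 of 13396 genes (1198 higher and 1379 lower). There were 1603, 1485 and 1707 without drug-treated libraries 1, 2 and 3 in turn and 686, 1616 and 1083 without naive libraries 1, 2 and 3 in turn. A fit of these groups alone called 4484.

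Resistant Braf/Pten tumors, from mice given PBS, held fewer transcripts of lymphocytes and of antigen presentation than naive tumors. Cytotoxic (11 of 12 lower, camera adjusted p = 7.9e-09), T cell (10 of 11 lower, camera adjusted p = 1.1e-06), NK cell (4 of 6 lower, 6 lower adjusted over the list alone, camera adjusted p = 0.00061) and macrophage genes (10 of 16 lower, 11 lower adjusted over the list alone, camera adjusted p = 1.8e-05) were lower. Each had adjusted p = 0.489 with r estimated. Perforin (Prf1) was at 0.429 ± 0.539 against 15.3 ± 3.43 CPM (SD, n = 4 and 3) and granzyme A (Gzma) 34.2-fold lower (adjusted p = 0.00305). MHC class I (12 of 13 lower, camera adjusted p = 2.7e-07), class II (6 of 7 lower, camera adjusted p = 0.00081), interferon-gamma response (11 of 16 lower, 15 lower adjusted over the list alone, camera adjusted p = 8.4e-08) and antiviral genes (5 of 19 lower, camera adjusted p = 9.6e-06) fell, with adjusted p from 0.489 to 0.512 with r estimated. Psmb9 was at -3.76 ± 0.66 and the peptide transporter Tap2 at -2.95 ± 0.36. The T cell attractants Cxcl9 and Ccl5 stood at -5.42 ± 0.68 and -3.75 ± 0.82 (adjusted p = 0.00252 and 0.0115). Type 1 dendritic cell genes were lower too (2 of 10 lower, 6 lower adjusted over the list alone, camera adjusted p = 0.00088 and adjusted p = 0.504 with r estimated). Hypoxia genes were higher (4 of 10 higher, camera adjusted p = 0.0235 and adjusted p = 0.581 with r estimated). The angiogenic factor Vegfa was 2.38-fold higher and the glucose transporter Slc2a1 stood at 1.32 ± 0.30. A total of 3179 of 13396 genes (1623 higher and 1556 lower) differed, against 1643, 1152 and 1202 without naive libraries 1, 2 and 3 in turn and 1947 without resistant library 4. The resistant tumors carried another title code than the naive ones, so that this difference and a batch cannot be told apart.

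Resistant Braf cells (100 nM dabrafenib) differed from naive ones in dedifferentiation and cytokine genes, and no antiviral gene was called lower. Serpine1, an inhibitor of matrix breakdown, was 10.8-fold higher, the matrix protein Tnc 72.5-fold higher and Wnt5a 4.06-fold higher (adjusted p = 8.5e-12, 1.6e-12 and 7.7e-10). Dedifferentiation and invasion genes were higher as a list (6 higher and 2 lower of 10, 7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00373). Cytokines rose (8 higher and 1 lower of 12, camera adjusted p = 0.011 and adjusted p = 0.107 with r estimated). Csf1 was at 346 ± 5.71 against 88.4 ± 26.2 CPM (SD, n = 3 each) and Cxcl12 4.57-fold higher, while the alarmin Il33 was 31.2-fold lower. Antiviral genes that passed were higher (6 of 19 higher, camera adjusted p = 0.0657), such as Ifit2 at 0.73 ± 0.18 and Isg15 at 1.38 ± 0.40. MHC class I genes went both ways (6 higher and 3 lower of 13, 7 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0906). H2-D1 stood at 1.29 ± 0.13 and the proteasome subunit Psmb10 at -0.82 ± 0.17. Cell cycle genes were lower (1 higher and 12 lower of 18, camera adjusted p = 0.0008), among them Cdk1 (2.01-fold lower). The fit called 4969 of 10605 genes (2571 higher and 2398 lower). Resistant Braf cells labelled as coming from an NSG mouse, a strain without lymphocytes, differed from the other resistant cells in 2798 genes (1525 higher and 1273 lower). Higher in them were Myl9 (6.47 ± 0.22) and Cnn1 (6.42 ± 0.23), with adjusted p = 4.1e-15 and 6.4e-14. MHC class I genes were lower (1 higher and 5 lower of 13, camera adjusted p = 0.00184 and adjusted p = 0.121 with r estimated). H2-K1 was at 7.35 ± 2.57 against 51.5 ± 5.36 CPM (SD, n = 3 each).

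Interferon in naive Braf cells raised Gbp7 from 2.09 ± 0.347 to 964 ± 14 CPM (SD, n = 3 each). It raised Irf1, a transcription factor of the response, 52.4-fold and H2-K1 21-fold (adjusted p = 1.9e-21 and 1.8e-18). The immunoproteasome gene Psmb9 had no read in naive cells and was at least 1440-fold higher. In all, 19 of 19 antiviral genes rose (median 7.28, or 5.06 with members that have no read in 1 group at their bound, camera adjusted p = 3.1e-37). So did 13 of 13 class I (camera adjusted p = 1.9e-31) and interferon-gamma response genes (14 of 15 higher, 15 higher adjusted over the list alone, camera adjusted p = 6.8e-37). In total 2283 of 10605 genes (1196 higher and 1087 lower) changed. There were 1442 and 1491 without naive interferon libraries 1 and 3 in turn, and 1237 when only these groups were fitted. Resistant Braf cells raised the same 3 lists, antiviral (19 of 19 higher, camera adjusted p = 3.1e-47), class I (13 of 13 higher, camera adjusted p = 9.8e-40) and interferon-gamma response (14 of 15 higher, camera adjusted p = 4.6e-49). Gbp7 was 416-fold higher, Isg15 106-fold higher and the monocyte attractant Ccl2 22.4-fold higher (adjusted p = 2.2e-22, 3.9e-18 and 4.7e-11). In all 1128 of 10605 genes (754 higher and 374 lower) changed, and 1759 when only these groups were fitted. A difference of response between resistant and naive cells was called in 278 genes, 141 with a positive and 137 with a negative difference (resistant minus naive). Among the negative were the chemokine Cx3cl1 (-2.65 ± 0.24), Tap1 (-2.16 ± 0.55) and H2-D1 (-0.88 ± 0.17). Among the positive were the matrix genes Fbln5 (1.68 ± 0.29) and Col11a1 (1.81 ± 0.45). Tap1 ended at 268 ± 7.92 CPM in resistant and 261 ± 22.1 CPM in naive cells (SD, n = 3 each) from 1.76 ± 0.733 and 0.351 ± 0.321 CPM. There were 185 without naive library 2, 162 and 154 without resistant interferon libraries 1 and 2 in turn, 155 and 154 without resistant libraries 1 and 2 in turn and 151, 753 and 166 without naive interferon libraries 1, 2 and 3 in turn. Without a filter on low counts the number was 482.

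In whole Braf tumors, 3 days of dabrafenib lowered cell cycle genes (6 of 18 lower, 17 lower adjusted over the list alone, camera adjusted p = 1.4e-16 and adjusted p = 0.671 with r estimated). Cdc20 was at 8.7 ± 2.61 against 66.6 ± 36.5 CPM (SD, n = 3 each) and Mki67 4.5-fold lower (adjusted p = 0.0431 and 0.0431). The matrix protein Thbs1 rose (1.29 ± 0.22). Antiviral genes were lower only over their own list (0 of 19 called, 17 lower adjusted over the list alone, camera adjusted p = 1.1e-13 and adjusted p = 0.671 with r estimated). Rsad2 stood at -1.99 ± 0.43 with adjusted p = 0.0766. No T cell marker was called (0 of 9 called, camera adjusted p = 0.951). Cd8a was at 7.03 ± 1.85 against 8.3 ± 3.71 CPM (SD, n = 3 each). Only 51 of 11524 genes passed (5 higher and 46 lower). That number was 0 when these groups were fitted alone, 324 with DESeq2 and 113 without a filter. There were 0, 0 and 0 without drug-treated libraries 1, 2 and 3 in turn and 0, 0 and 212 without naive libraries 1, 2 and 3 in turn. Resistant Braf tumors had lower antiviral genes (17 of 19 lower, 19 lower adjusted over the list alone, camera adjusted p = 6.5e-19 and adjusted p = 0.75 with r estimated). Irf7, a regulator of interferon genes, was at 14.1 ± 2.6 against 130 ± 52.4 CPM (SD, n = 3 each) and Ifit3 9.92-fold lower (adjusted p = 0.00115 and 0.00124). Of type 1 dendritic cell genes, 2 of 7 were lower (3 adjusted over the list alone). Camera adjusted p was 0.00219, or 0.826 with r estimated. Cadm1 was at -1.99 ± 0.20 and Tlr3 at -2.12 ± 0.32, in which cells was not tested. The activation list was lower too (2 of 11 lower, 4 lower adjusted over the list alone, camera adjusted p = 0.00964 and adjusted p = 0.826 with r estimated), with the interleukin-12 subunit Il12b at -2.61 ± 0.64. T cell markers were not called (0 of 9 called, camera adjusted p = 0.274). Tnc and the fibroblast receptor Pdgfra were higher (1.70 ± 0.44 and 1.12 ± 0.25). In total 864 of 11524 genes (450 higher and 414 lower) differed, and 1304 with DESeq2. There were 338 and 415 without naive libraries 2 and 3 in turn and 505 and 465 without resistant libraries 1 and 3 in turn.

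In resistant CT26 cells (10 nM trametinib) ERK target genes were lower and interferon-stimulated genes higher than in naive cells. ERK targets fell without exception (16 of 16 lower, camera adjusted p = 3.3e-12). The ERK phosphatase Dusp6 was at 53.8 ± 3.56 against 219 ± 9.35 CPM (SD, n = 3 each) and Egr1 13.2-fold lower (adjusted p = 1.9e-13 and 5.1e-10). Antiviral genes rose (18 of 19 higher, camera adjusted p = 2.9e-12). Irf7 was at 69.3 ± 19 against 6.84 ± 0.202 CPM (SD, n = 3 each) and Oasl2, of the RNA-sensing OAS family, 12.7-fold higher. Interferon-gamma response (12 of 14 higher, camera adjusted p = 8.4e-07) and MHC class I genes (11 of 13 higher, camera adjusted p = 6.3e-05) were higher, among them Psmb8 (11.5-fold higher) and Tap1 (4.16-fold higher). Thbs1 and the secreted glycoprotein Fstl1 were 50.3-fold higher and 63.4-fold higher, and Ccl2 was 74.3-fold higher (counting interval 13 to 2971). The fit called 4669 of 10036 genes (2518 higher and 2151 lower).

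Interferon raised every MHC class I (13 of 13 higher, camera adjusted p = 9.9e-30), antiviral (19 of 19 higher, camera adjusted p = 1.4e-44) and interferon-gamma response gene (14 of 14 higher, camera adjusted p = 3.3e-36) in naive CT26 cells. Iigp1 rose 982-fold and Rsad2 48.9-fold (adjusted p = 2.9e-19 and 8e-17). The fit called 968 of 10036 genes (609 higher and 359 lower). In resistant cells class I (13 of 13 higher, camera adjusted p = 3.8e-34), antiviral (17 of 19 higher, 18 higher adjusted over the list alone, camera adjusted p = 5.2e-25) and interferon-gamma genes (14 of 14 higher, camera adjusted p = 1.3e-38) rose too, Iigp1 40.7-fold and Rsad2 3.88-fold. Egr1 was 6.09-fold higher, among 559 of 10036 genes (399 higher and 160 lower). The response was smaller in resistant cells for antiviral (18 of 19 lower, 19 lower adjusted over the list alone, camera adjusted p = 2.7e-40), interferon-gamma (9 of 14 lower, 10 lower adjusted over the list alone, camera adjusted p = 4.8e-13) and class I genes (7 of 13 lower, 1 higher and 8 lower adjusted over the list alone, camera adjusted p = 1.6e-08), from the higher start described above. Rsad2 reached 253 ± 22.1 CPM in resistant and 450 ± 41.1 CPM in naive cells, from 65.6 ± 15.9 and 8.88 ± 2.94 CPM (SD, n = 3 each). Tap1 reached 302 ± 14.9 and 254 ± 5.06 CPM (SD, n = 3 each). Egr1 rose more in resistant cells (1.85 ± 0.38), and for Epha2, which fell in naive cells, the difference was 1.37 ± 0.26. In all, the response differed for 225 of 10036 genes (63 higher and 162 lower), and for 423 without a filter.

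Trametinib for 3 days (1 mg/kg) lowered cell cycle genes (17 of 18 lower, 18 lower adjusted over the list alone, camera adjusted p = 9.7e-13) and ERK targets (1 higher and 6 lower of 16, 1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00023) in whole CT26 tumors. Cdk1 was at 118 ± 9.28 against 318 ± 40.7 CPM (SD, n = 3 each) and Etv4, an ETS factor downstream of ERK, 2.77-fold lower (adjusted p = 0.00014). T cell (6 of 10 higher, 8 higher adjusted over the list alone, camera adjusted p = 0.00122), cytotoxic (3 of 9 higher, camera adjusted p = 0.00606), fibroblast (5 of 9 higher, 6 higher adjusted over the list alone, camera adjusted p = 0.0124) and skeletal muscle markers (7 of 7 higher, camera adjusted p = 0.00023) rose in the same libraries. All these lists had adjusted p = 0.676 with r estimated. Cd3g of T cells rose 5.1-fold and Cd8b1 3.34-fold. The muscle protein Ttn stood at 107 ± 53.9 against 3.93 ± 3.68 CPM (SD, n = 3 each). Of 10808 genes 2161 changed (929 higher and 1232 lower). There were 1072 and 1024 without drug-treated libraries 1 and 2 in turn and 1086 without naive library 2. Resistant CT26 tumors had lower macrophage (11 of 16 lower, camera adjusted p = 0.00013), fibroblast (6 of 9 lower, 8 lower adjusted over the list alone, camera adjusted p = 0.00096), type 1 dendritic cell (3 of 6 lower, 4 lower adjusted over the list alone, camera adjusted p = 0.0311) and antiviral genes (9 of 19 lower, 13 lower adjusted over the list alone, camera adjusted p = 2.7e-05) than naive tumors. Each list had adjusted p = 0.825 with r estimated. Csf1r was 3.02-fold lower, Col1a1 3.83-fold lower and Irf7 2.73-fold lower (adjusted p = 0.00414, 0.00026 and 0.00748). Granzymes rose instead, Gzmf 91.5-fold and Gzmc 23.1-fold, in a cytotoxic list that split (2 higher and 1 lower of 9, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.865). T cell markers were not called (0 of 10 called, camera adjusted p = 0.188), with Lck at -0.62 ± 0.43. A total of 2112 of 10808 genes (1132 higher and 980 lower) differed, against 1033 and 1158 without naive libraries 1 and 3 in turn and 1326 without resistant library 2.

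Genes called for resistance were compared between models, each count beside its ratio to the product n1 x n2 / N. In vitro 10378 genes were tested in both Braf/Pten and Braf cells, where 971 (1.29) were higher and 729 (1.22) lower in both, and 584 (0.85) and 596 (0.91) went opposite ways. For Braf/Pten and CT26 cells 987 (1.38) and 751 (1.42) went the same and 455 (0.75) and 523 (0.84) opposite ways. For Braf and CT26 cells opposite calls, 581 (1.21) and 598 (1.13), exceeded the product by more than calls the same way, 617 (1.11) and 464 (1.02). In whole tumors calls the same way were above the product in each pair, with 104 (1.77) and 80 (1.76) for Braf/Pten and Braf, 244 (1.66) and 233 (2.08) for Braf/Pten and CT26 and 68 (1.87) and 87 (2.92) for Braf and CT26. Opposite calls, 28 (0.53) and 31 (0.61), 51 (0.40) and 73 (0.56), and 35 (1.14) and 12 (0.34), were below it except those higher in Braf and lower in CT26 tumors. No test was made of these overlaps, as genes are not independent.

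CD103+ dendritic cells from resistant Braf/Pten tumors had lower genes of type 1 dendritic cells, of their activation and of antigen presentation than those from naive tumors. The type 1 list fell (10 of 10 lower, camera adjusted p = 1.1e-07 and adjusted p = 0.0665 with r estimated). The chemokine receptor Xcr1 was at 26.9 ± 20.2 against 504 ± 154 CPM (SD, n = 14 and 11) and Irf8, a transcription factor these cells depend on, 5.26-fold lower (adjusted p = 1.4e-13 and 3.1e-14). Activation genes fell (12 of 13 lower, camera adjusted p = 1.3e-07 and adjusted p = 0.0665 with r estimated). Among them were Il12b (82.8-fold lower), Ccl22 (112-fold lower) and the costimulatory receptor Cd40 (8.59-fold lower). MHC class II (6 of 7 lower, camera adjusted p = 8.8e-05 and adjusted p = 0.24 with r estimated) and class I genes (13 of 13 lower, camera adjusted p = 2.2e-10 and adjusted p = 0.0602 with r estimated) were lower. H2-K1 was at -1.27 ± 0.10 and Cd74, the class II chaperone, at -2.31 ± 0.38. Antiviral (19 of 19 lower, camera adjusted p = 1.4e-10 and adjusted p = 0.0602 with r estimated) and interferon-gamma genes (15 of 16 lower, camera adjusted p = 1.1e-07) were lower too, with Irf7 11.1-fold lower. Macrophage genes were higher in part (9 higher and 1 lower of 16, camera adjusted p = 0.115), Mafb at 1569 ± 1046 against 105 ± 39.4 CPM (SD, n = 14 and 11). So were neutrophil genes, neither list being called (6 higher and 1 lower of 7, camera adjusted p = 0.383). Genes of type 2 and plasmacytoid dendritic cells split (3 higher and 4 lower of 8, camera adjusted p = 0.747), Klf4 at 1.41 ± 0.20 and Mgl2 at -3.14 ± 0.39. Il11, also high in resistant tumor cells, rose 38.9-fold (source not tested). The fit called 5991 of 10240 genes (3366 higher and 2625 lower), with a median log2 fold of 0.11 over all genes.

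Poly I:C, a double-stranded RNA mimic (50 ug, 24 h), raised interferon genes in these cells from resistant tumors but not the type 1 list. All antiviral (19 of 19 higher, camera adjusted p = 8.3e-32) and interferon-gamma genes (16 of 16 higher, camera adjusted p = 1.4e-20) rose. Irf7 went from 68.3 ± 48.5 to 2364 ± 769 CPM (SD, n = 14 and 11) and Cxcl9 104-fold (adjusted p = 7.1e-16 and 4.6e-15). MHC class I (11 of 13 higher, 12 higher adjusted over the list alone, camera adjusted p = 9.5e-14) and activation genes (8 of 13 higher, camera adjusted p = 0.00011 and adjusted p = 0.18 with r estimated) rose. H2-K1 was raised 4.05-fold and Cd40 4.01-fold. Class II genes fell (7 of 7 lower, camera adjusted p = 0.0643), H2-Ab1 at -1.27 ± 0.37. Only 6 of 10 type 1 dendritic cell genes fell, not as a list (camera adjusted p = 0.0664), Xcr1 4.27-fold and Clec9a 8.71-fold. Cell cycle genes fell (17 of 18 lower, camera adjusted p = 6.5e-15), with Top2a 4.35-fold lower. Neutrophil (5 of 7 higher, camera adjusted p = 3.6e-05) and macrophage genes (7 higher and 1 lower of 16, 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00471 and adjusted p = 0.333 with r estimated) rose and fibroblast genes fell (7 of 8 lower, camera adjusted p = 5.6e-05 and adjusted p = 0.0849 with r estimated) in the same libraries. S100a8 was at 521 ± 893 against 8.12 ± 11.6 CPM (SD, n = 11 and 14). In all 2753 of 10240 genes (1377 higher and 1376 lower) changed.

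Among CD45+ cells, those of resistant Braf/Pten tumors had lower genes of NK cells, T cells and type 1 dendritic cells and higher neutrophil genes. NK cell genes fell (6 of 6 lower, camera adjusted p = 3.4e-08), Klrk1 at 1.55 ± 1.86 against 31.4 ± 8.11 CPM (SD, n = 3 each) and Ncr1 11.6-fold lower (adjusted p = 0.00019 and 0.00311). T cell (4 of 11 lower, 5 lower adjusted over the list alone, camera adjusted p = 0.00034 and adjusted p = 0.173 with r estimated) and cytotoxic genes (5 of 11 lower, camera adjusted p = 4.9e-06 and adjusted p = 0.0915 with r estimated) were lower. Lck was 14.6-fold lower and Gzma 30-fold lower. Type 1 dendritic cell (7 of 10 lower, 9 lower adjusted over the list alone, camera adjusted p = 1.4e-08) and MHC class II genes (7 of 7 lower, camera adjusted p = 1.7e-08 and adjusted p = 0.0715 with r estimated) fell. Batf3, a factor type 1 dendritic cells need, was at -3.86 ± 0.66 and H2-Aa at -2.56 ± 0.40. Neutrophil genes were higher (5 of 9 higher, 7 higher adjusted over the list alone, camera adjusted p = 2.1e-05 and adjusted p = 0.109 with r estimated), Cxcr2 at 2.39 ± 0.56. Arginase (Arg1) rose, at 947 ± 339 against 43.4 ± 3.11 CPM (SD, n = 3 each), in a macrophage list with few calls (2 of 16 higher, camera adjusted p = 0.0637). Dissociation stress genes were higher as well (3 of 11 higher, 6 higher adjusted over the list alone, camera adjusted p = 0.00104 and adjusted p = 0.201 with r estimated). A total of 1154 of 10936 genes (537 higher and 617 lower) differed, and 2276 when only these groups were fitted. There were 527, 598 and 757 without naive libraries 1, 2 and 3 in turn and 682 without resistant library 1.

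At 2.5 days after T cell transfer, CD45+ cells of naive tumors had gained cytotoxic (6 of 11 higher, 10 higher adjusted over the list alone, camera adjusted p = 1.1e-16) and interferon-gamma response transcripts (12 of 16 higher, 16 higher adjusted over the list alone, camera adjusted p = 1.2e-26). Gzma rose from 35.1 ± 21.7 to 905 ± 141 CPM (SD, n = 3 each). Ifng itself rose 25.9-fold and Cxcl9 36.5-fold (adjusted p = 0.00464 and 0.00019). MHC class I genes rose (8 of 13 higher, 13 higher adjusted over the list alone, camera adjusted p = 5.8e-16), and 229 of 10936 genes (165 higher and 64 lower) changed. There were 99, 139 and 140 without naive day 2.5 libraries 1, 2 and 3 in turn and 106, 87 and 152 without naive libraries 1, 2 and 3 in turn. There were 453 with DESeq2, 466 without a filter and 1879 from these groups alone. In resistant tumors transfer raised interferon-gamma response (15 of 16 higher, 16 higher adjusted over the list alone, camera adjusted p = 2.6e-32), class I (12 of 13 higher, 13 higher adjusted over the list alone, camera adjusted p = 1.1e-22), class II (7 of 7 higher, camera adjusted p = 8.9e-18) and type 1 dendritic cell genes (5 of 10 higher, 7 higher adjusted over the list alone, camera adjusted p = 1.7e-07). H2-Aa went from 176 ± 120 to 2526 ± 727 CPM (SD, n = 3 each). Cytotoxic genes rose (6 of 11 higher, 8 higher adjusted over the list alone, camera adjusted p = 2.3e-09), Gzma to 38 ± 6.78 CPM (SD, n = 3). Neutrophil genes fell (5 of 9 lower, 6 lower adjusted over the list alone, camera adjusted p = 1.4e-05 and adjusted p = 0.129 with r estimated), S100a8 9.97-fold lower. Here 615 of 10936 genes (437 higher and 178 lower) changed, and 363 without resistant library 1. A difference of this change between resistant and naive tumors was called in 21 genes (18 higher and 3 lower). Iigp1 was at 5.74 ± 0.61, H2-Aa at 2.92 ± 0.55 and the T cell costimulator Tnfrsf9 at -3.02 ± 0.52. There were 6, 11 and 8 without naive day 2.5 libraries 1, 2 and 3 in turn, 9, 6 and 10 without naive libraries 1, 2 and 3 in turn, 37 without resistant day 2.5 library 3 and 10 and 8 without resistant libraries 1 and 3 in turn. There were 118 with DESeq2, 159 without a filter and 181 from these groups alone.

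Sorted GFP+ tumor cells of resistant Braf/Pten tumors had lower antiviral genes than those of naive tumors (18 of 19 lower, camera adjusted p = 1.4e-11 and adjusted p = 0.367 with r estimated). Rsad2 was at 4.17 ± 3.2 against 91.6 ± 32.1 CPM (SD, n = 3 each) and Stat1, the interferon signal carrier, 9.52-fold lower (adjusted p = 0.0007 and 0.00611). Interferon-gamma (8 of 15 lower, camera adjusted p = 0.00076 and adjusted p = 0.468 with r estimated) and MHC class I genes (6 of 13 lower, camera adjusted p = 0.00012 and adjusted p = 0.443 with r estimated) were lower. H2-K1 was at -2.40 ± 0.40. Dedifferentiation genes were higher (7 of 11 higher, 7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00599 and adjusted p = 0.114 with r estimated). Tgfbi was at 1.67 ± 0.32, and the cytokine Il11 was 185-fold higher. Macrophage (5 of 10 lower, 8 lower adjusted over the list alone, camera adjusted p = 0.021) and fibroblast genes (1 higher and 5 lower of 9, camera adjusted p = 0.0247) were lower in the same libraries, with adjusted p from 0.443 to 0.481 with r estimated. Lyz2 was at 1.72 ± 1.71 against 18 ± 23.3 CPM (SD, n = 3 each). In all 2249 of 10646 genes (1136 higher and 1113 lower) differed, and 3464 from these groups alone. There were 1336 without naive library 3 and 1328, 1455 and 1489 without resistant libraries 1, 2 and 3 in turn. At 2.5 days after transfer naive tumor cells raised MHC class I (12 of 13 higher, 13 higher adjusted over the list alone, camera adjusted p = 5.4e-41), interferon-gamma (13 of 15 higher, 15 higher adjusted over the list alone, camera adjusted p = 4.3e-39) and antiviral genes (4 of 19 higher, 19 higher adjusted over the list alone, camera adjusted p = 1.7e-23). In them H2-D1 went from 336 ± 108 to 1496 ± 286 CPM (SD, n = 3 each). Resistant cells raised class I (12 of 13 higher, 13 higher adjusted over the list alone, camera adjusted p = 1.6e-35), interferon-gamma (12 of 15 higher, 14 higher adjusted over the list alone, camera adjusted p = 3.7e-35) and antiviral genes (1 of 19 higher, 14 higher adjusted over the list alone, camera adjusted p = 1.3e-12 and adjusted p = 0.223 with r estimated) as well. Here H2-D1 went from 52 ± 11.4 to 336 ± 111 CPM (SD, n = 3 each). The fit called 121 of 10646 genes (116 higher and 5 lower) in naive cells, with 69 and 75 without naive day 2.5 libraries 1 and 2 in turn and 70 and 56 without naive libraries 1 and 2 in turn. There were 188 by DESeq2, 193 without a filter and 313 from these groups alone. In resistant cells 97 of 10646 genes (83 higher and 14 lower) changed, with 158 without resistant day 2.5 library 1 and 53, 57 and 57 without resistant libraries 1, 2 and 3 in turn. The alternatives gave 192 by DESeq2, 182 without a filter and 53 from these groups alone. No gene passed for a difference between the responses by edgeR (397 with unadjusted p < 0.05). In turn 12 did by DESeq2, 6 without a filter, 1 from these groups alone, and 3, 1 and 1 without resistant day 2.5 libraries 1, 2 and 3 in turn. Iigp1 stood at 4.19 ± 0.91 for this difference (adjusted p = 0.377).

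CD8+ T cells sorted from resistant tumors 72 h after transfer had lower cytotoxic genes than those from naive tumors (7 of 12 lower, 8 lower adjusted over the list alone, camera adjusted p = 7.9e-06 and adjusted p = 0.0935 with r estimated). Gzma was at 98.6 ± 68.3 against 340 ± 110 CPM (SD, n = 9 and 12). Ccl5 and Nkg7, a protein of cytotoxic granules, were 11.8-fold lower and 3.46-fold lower (adjusted p = 1.3e-05 and 4.2e-05). Macrophage genes were higher in the same libraries (13 higher and 1 lower of 15, camera adjusted p = 2.7e-11 and adjusted p = 0.0686 with r estimated), Csf1r at 475 ± 713 against 14.1 ± 8.47 CPM (SD, n = 9 and 12), highest in library 9 (log2 fold 5.05, or 4.00 without libraries 7 and 9). So were neutrophil genes (3 of 4 higher, camera adjusted p = 0.00442 and adjusted p = 0.141 with r estimated) and 2 of 2 fibroblast genes, Col1a2 62.6-fold higher and Col3a1 20.2-fold higher. Exhaustion genes were higher in part (2 of 11 higher, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.944), with the inhibitory receptors Pdcd1 at 1.69 ± 0.38 and Cd244 at 2.42 ± 0.69. Cell cycle (4 of 18 lower, 5 lower adjusted over the list alone, camera adjusted p = 0.00055 and adjusted p = 0.397 with r estimated) and antiviral genes (2 of 16 lower, 1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00026 and adjusted p = 0.208 with r estimated) were lower in part. Mcm2 was at -0.89 ± 0.25 and Ifit2 at -1.79 ± 0.42. Dissociation stress genes were higher (3 of 11 higher, 4 higher adjusted over the list alone, camera adjusted p = 0.00573 and adjusted p = 0.255 with r estimated), Fos 4.27-fold higher. In all 1297 of 9470 genes (847 higher and 450 lower) differed, and 2774 without a filter. Resistant library 9 stood apart, with a cell cycle mean of 1.71 log2 CPM against 6.75 to 7.54 in the other resistant libraries. Without libraries 7 and 9, 1744 genes were called, with macrophage genes 12 of 15 higher and cytotoxic genes 8 of 12 lower.

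**Figure D1:**
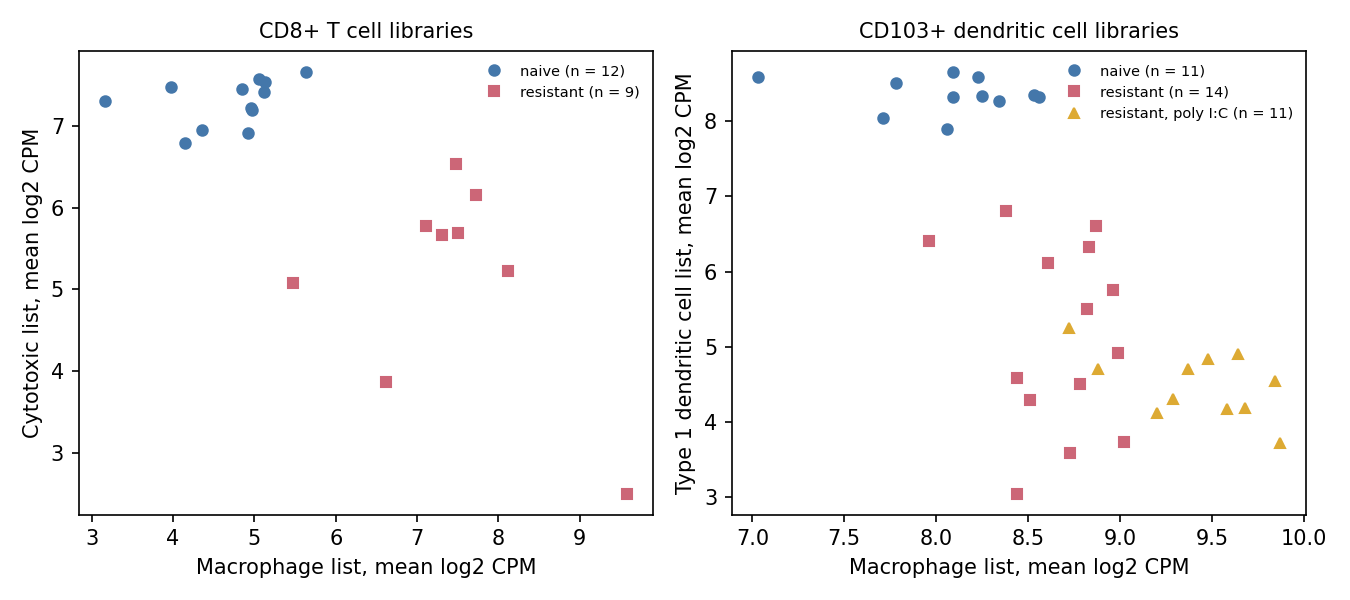
Mean log2 CPM of the macrophage list (x) against the cytotoxic list in CD8+ T cell libraries (left) and the type 1 dendritic cell list in CD103+ libraries (right), 1 point per library. Resistant T cell libraries lie at 6.53 or below for the cytotoxic list and naive ones at 6.79 to 7.66. Resistant CD103+ libraries lie at 3.05 to 6.80 for the type 1 list and naive ones at 7.90 to 8.65.

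In sorted resistant Braf/Pten tumor cells, trametinib for 3 days (1 mg/kg) raised matrix and interferon genes and lowered proliferation genes. Cell cycle genes (18 of 18 lower, camera adjusted p = 1.5e-08) and ERK targets (1 higher and 9 lower of 16, 1 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.00268) fell, with adjusted p from 0.221 to 0.277 with r estimated. Cdk1 was at 11.7 ± 6.85 against 102 ± 27.3 CPM (SD, n = 6 and 5) and Ccnd1 5.7-fold lower (adjusted p = 1.3e-07 and 9.3e-11). Antiviral (15 of 15 higher, camera adjusted p = 3.1e-07), MHC class I (7 of 10 higher, camera adjusted p = 0.00213), interferon-gamma (10 higher and 2 lower of 12, camera adjusted p = 0.00101) and fibroblast-list matrix genes (9 of 9 higher, camera adjusted p = 2.2e-05) rose, with adjusted p from 0.221 to 0.277 with r estimated. Ifih1, a sensor of viral RNA, rose 28.4-fold. Tapbp, which loads peptides onto class I, was at 3.12 ± 0.17. The matrix protein Postn was at 2977 ± 234 against 1.63 ± 1.47 CPM (SD, n = 6 and 5). Il11 fell from 3797 ± 613 to 28 ± 21.2 CPM (SD, n = 5 and 6). Areg, a ligand of the EGF receptor, was 130-fold lower. Trametinib library 5 had the highest antiviral mean, 6.14 log2 CPM against 3.82 to 4.67. In all 5847 of 10365 genes (3003 higher and 2844 lower) changed.

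In tumors of Rag2-/- mice resistant tumor cells had lower antiviral (19 of 19 lower, camera adjusted p = 3.3e-10), MHC class I (13 of 13 lower, camera adjusted p = 1.3e-05), interferon-gamma (10 of 15 lower, 12 lower adjusted over the list alone, camera adjusted p = 0.00011) and fibroblast-list genes (8 of 9 lower, camera adjusted p = 0.00029) than naive ones, with adjusted p from 0.343 to 0.44 with r estimated. Dissociation stress genes were lower too (7 of 11 lower, 8 lower adjusted over the list alone, camera adjusted p = 0.0267 and adjusted p = 0.739 with r estimated). The antiviral median was -6.79, and Ifit1 was at 0.13 ± 0.126 against 53.9 ± 13.7 CPM (SD, n = 3 each). H2-K1 was 15-fold lower and Postn 58-fold lower (adjusted p = 0.00011 and 2.3e-06). Il11 was 148-fold higher and Ptges, a prostaglandin E synthase, 11.1-fold higher (adjusted p = 7e-05 and 4.1e-07). The opioid precursor Penk was 3210-fold lower. The fit called 5539 of 12210 genes (2629 higher and 2910 lower). Trametinib (0.5 mg/kg, 72 h) lowered cell cycle genes (18 of 18 lower, camera adjusted p = 2.7e-19) and ERK targets (7 of 18 lower, 8 lower adjusted over the list alone, camera adjusted p = 0.0167) in naive cells. It raised fibroblast-list (7 of 9 higher, 8 higher adjusted over the list alone, camera adjusted p = 4.1e-05) and macrophage genes (6 of 11 higher, 7 higher adjusted over the list alone, camera adjusted p = 0.029). These 4 lists had adjusted p from 0.15 to 0.399 with r estimated. Ccna2 was 56.5-fold lower, Etv5 4.13-fold lower. The macrophage lysozyme Lyz2 was at 32.7 ± 39.6 against 0.288 ± 0.25 CPM (SD, n = 3 each). It changed 3946 of 12210 genes (1843 higher and 2103 lower), or 2447 with the first technical library per mouse. In resistant cells trametinib raised antiviral (16 of 19 higher, camera adjusted p = 1.1e-05), MHC class I (8 of 13 higher, 9 higher adjusted over the list alone, camera adjusted p = 0.00332), interferon-gamma (9 of 15 higher, camera adjusted p = 0.00198) and matrix genes (8 of 9 higher, 9 higher adjusted over the list alone, camera adjusted p = 2e-06). It lowered cell cycle genes (17 of 18 lower, 18 lower adjusted over the list alone, camera adjusted p = 1.1e-07). These 5 lists had adjusted p from 0.226 to 0.936 with r estimated. Ifit1 rose to 27.1 ± 16.7 CPM and Irf7 from 0.512 ± 0.276 to 13 ± 6.19 CPM (SD, n = 3 mice each). Mcm2 was at -1.09 ± 0.13, among 4716 of 12210 genes (2549 higher and 2167 lower) that changed. The response differed between resistant and naive cells in 2212 of 12210 genes (1466 higher and 746 lower). The difference was positive for antiviral genes, which rose in resistant cells (16 of 19 higher, 17 higher adjusted over the list alone, camera adjusted p = 2.2e-08), and for cell cycle genes, which fell less in them (16 of 18 higher, 18 higher adjusted over the list alone, camera adjusted p = 7.1e-12), with adjusted p from 0.468 to 0.485 with r estimated. Irf7 was at 5.78 ± 0.90 and Mki67 at 4.00 ± 0.39. That number was 1429 without resistant library 2 and 1085 with the first technical library per mouse.

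**Figure D2:**
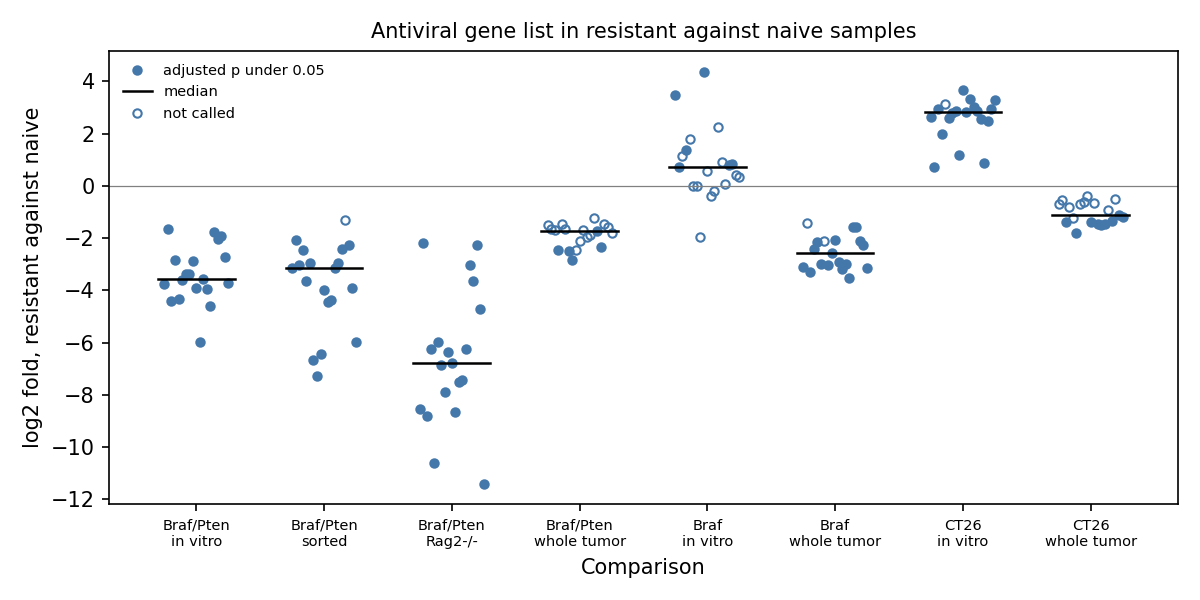
Fitted log2 folds of the antiviral list, resistant against naive, in 8 comparisons, with 1 point per gene (filled where adjusted p was under 0.05) and a line at the median. Medians lie below 0 in each Braf/Pten comparison and in whole Braf and CT26 tumors and above 0 in Braf and CT26 cells in vitro.

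RNA labelled for 90 min showed more transcripts of 8 of 15 ERK targets in resistant than naive Braf/Pten cells (camera adjusted p = 0.00544). In the cells above this list fell. Dusp5 was at 3.47 ± 0.22 and Egr1 at 3.11 ± 0.28 (adjusted p = 5.2e-20 and 7.5e-14). Cytokines were higher (5 higher and 1 lower of 7, camera adjusted p = 0.00248), Ptgs2 7.13-fold higher and Csf1 4.93-fold higher. B2m was at -1.47 ± 0.22 in the class I list (1 of 4 lower, 2 lower adjusted over the list alone, camera adjusted p = 0.00248). Cell cycle genes were lower (3 higher and 7 lower of 18, 3 higher and 8 lower adjusted over the list alone). Camera adjusted p was 0.00676, or 0.108 with r estimated. A MEK inhibitor (100 nM, 2 h) lowered ERK targets in naive (14 of 15 lower, camera adjusted p = 4.5e-26) and resistant cells (12 of 15 lower, 13 lower adjusted over the list alone, camera adjusted p = 6.9e-17), Dusp6 29.2-fold lower and 31.5-fold lower. Cytokines were not called as a list in naive (2 of 7 lower, 1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.86) or resistant cells (1 higher and 4 lower of 7, camera adjusted p = 0.372). Ptgs2 was at -1.14 ± 0.21 and -0.91 ± 0.17 in turn. Csf1 was at -0.67 ± 0.20 in resistant cells, but at 0.0727 in all reads and, scaled by converted reads, -0.53 (adjusted p = 0.0734). For neither was a difference between the cells called (adjusted p = 0.708 and 0.971). A difference of the inhibitor's effect was called in 255 of 6759 genes (150 higher and 105 lower), with Ccnd1 at 2.74 ± 0.27 (0.196 in all reads, adjusted p = 0.39) and Dusp5 at -1.85 ± 0.38. That number was 165 without naive MEK inhibitor library 1, 396 without resistant DMSO library 2 and 155 without resistant MEK inhibitor library 3. In all 1935 of 6759 genes (1520 higher and 415 lower) differed between the cells. The inhibitor changed 275 of 6759 genes (29 higher and 246 lower) in naive and 744 of 6759 genes (170 higher and 574 lower) in resistant cells. For naive cells there were 167 and 154 without naive DMSO libraries 2 and 3 in turn and 168, 157 and 170 without naive MEK inhibitor libraries 1, 2 and 3 in turn. For resistant cells there were 448 without resistant MEK inhibitor library 1. All reads gave 6094 between the cells, 127 and 1410 with the inhibitor and 2439 for the difference, and the compared groups alone 455 for naive cells. Scaling by all reads left median log2 folds over all genes of 0.32, -0.18 and -0.14. Relative to those medians Egr1 was 2.79 higher in resistant cells. Taking replicate numbers as blocks, coded so after a first count was seen, gave 1850, 232, 663 and, for the difference of effects, 209 genes. Scaled by converted reads, the same 3 comparisons had 1631 (902 higher and 729 lower), 196 (68 higher and 128 lower) and 644 (284 higher and 360 lower).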

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

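The tests without libraries 7 and 9, in Rag2-/- mice, within title codes, in cells from untreated mice, of unequal folds and without shallow libraries, and the reading of the correlation by its interval, were chosen only after the result was seen.

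Some libraries stood far from the others of their group. Among 165 Dixon tests 17 did so (10.3 percent), where chance marks about 1 in 20 groups. Naive Braf/Pten library 1 in vitro had a total count of 28998268, library 6 had Cxcl12 at 5.53 and library 3 had Fosl1 at 7.43 log2 CPM. Of the resistant T cell libraries, library 9 was lowest in the means of cell cycle (1.71), dissociation stress (5.40), exhaustion (3.80) and naive or memory genes (3.25). It was also lowest in Ccl5 (-0.13), Ifit2 (-0.13), Nkg7 (7.19) and Pdcd1 (3.64) and highest in Csf1r (11.21). Library 7 was lowest in Fos (3.42) and Gzma (-0.13). Trametinib library 5 of sorted resistant tumor cells was highest in antiviral (6.14) and interferon-gamma response means (5.48) and in Ifih1 (6.12).

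Differences of response between resistant and naive material were called in 6 of 7 tests, for 3 of which the share of splits was not under 0.05 (below). There were 75 genes with interferon in Braf/Pten, 278 in Braf and 225 in CT26 cells, 21 with transfer in CD45+ cells, 2212 with trametinib in Rag2-/- mice and 255 with a MEK inhibitor in labelled RNA. With transfer in tumor cells edgeR called 0 (397 with unadjusted p < 0.05), and DESeq2 12.

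Groups in no comparison of the results held a signal too, every library lying above the untreated ones. In CD45+ cells 7 days after transfer the interferon-gamma response mean was higher by 2.81 in naive and 4.44 in resistant tumors (log2) and the cytotoxic mean by 2.60 and 3.81. At 9 days in resistant tumors these were 3.04 and 2.99. In resistant tumor cells the interferon-gamma mean was higher by 4.77 at 7 and 2.23 at 9 days, and in NSG-derived Braf cells with interferon by 7.01.

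Macrophage genes were higher and cytotoxic genes lower in CD8+ T cell libraries of resistant tumors. The 2 libraries apart were not the whole of it, since without them 12 of 15 macrophage genes were still called higher. Myeloid RNA carried past the CD3+ CD8+ gate is a candidate source. Over the 16 list genes, levels ranked as in CD45+ cells of resistant tumors of another series (Spearman 0.57, permutation p = 0.022, genes not independent). Lyz2 was at 1796 ± 1858 against 190 ± 151 CPM (SD, n = 9 and 12) and C1qb at 609 ± 362 against 73.6 ± 55.7 CPM (SD, n = 9 and 12). Whether such RNA also diluted the cytotoxic genes stays open, as T cell genes fell less by 0.71 (medians -0.71 and -1.42), between the values set for either reading, so a lower effector state of these T cells cannot be told apart from it.

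Antiviral genes were lower in resistant Braf/Pten cells in culture and in those sorted from tumors. Lost signals from T or B cells are not the whole cause, since the median was -6.79 in Rag2-/- mice. Nor are the title codes, with -2.44 and -5.14 within each. Drug does not explain tumor cells of mice given none (-3.16). In vitro it could (-3.81 with 48 h of dabrafenib, -3.55 in resistant cells). A loss of interferon signalling inside resistant cells, which still responded to added interferon, may be part of the fall and was not tested. Resistant cells of the other models did not share the fall in culture, with medians of 0.73 in Braf and 2.83 in CT26 cells, while in whole tumors 17 and 9 of 19 were lower in Braf and CT26 (medians -2.57 and -1.11).

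Type 1 dendritic cell genes were lower in CD103+ libraries of resistant tumors. Shallow libraries do not explain it, with 10 of 10 genes lower without them, and nor does dilution by cells lacking these genes as the whole cause, since the folds were unequal (chi-square per degree of freedom 6.1, from -4.16 in Xcr1 to -1.70 in Flt3). Macrophages in varying shares past the CD11c+ CD103+ gate remain possible, with Lyz2 at 2611 ± 1281 against 2799 ± 766 CPM (SD, n = 14 and 11). Over 14 resistant libraries their macrophage and type 1 means gave Pearson r = -0.15 (interval -0.63 to 0.42, permutation p = 0.62, Spearman -0.09, p = 0.76), the only correlation across libraries computed, and 0.34 without the 2 farthest libraries. An altered state of these cells and another cell mix cannot be told apart as causes.

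Other splits of the libraries were counted for each comparison, and given here is how many gave as many genes, with the real count and the highest of the others. Chance is excluded for these single effects. Resistance gave 1 of 40 with 6764 and 3709 (Braf/Pten cells) and 1 of 35 with 3179 and 2566 (Braf/Pten tumors). It gave 1 of 40 with 5991 and 4 (CD103+ cells) and 1 of 40 with 1297 and 0 (T cells). Naive Braf/Pten cells on drug gave 1 of 84 with 6202 and 3658. Poly I:C gave 1 of 40 with 2753 and 696 and trametinib in sorted resistant cells 1 of 40 with 5847 and 0. Interferon in Braf/Pten cells gave 3 of 84 with 1194 and 2987 (naive) and 2 of 84 with 601 and 3287 (resistant). Differences gave 1 of 21 with 75 and 1 (interferon, Braf/Pten cells), 225 and 92 (CT26 cells) and 2212 and 1640 (trametinib, Rag2-/- mice). The share was not under 0.05 in 4 differences of responses. It was 4 of 21 with 278 and 3113 for interferon in Braf cells and 2 of 21 with 21 and 24 for transfer in CD45+ cells. It was 21 of 21 with 0 and 0 for transfer in tumor cells and 4 of 21 with 255 and 2529 for MEK inhibition in labelled RNA. In Braf/Pten cells the highest other splits for interferon set the libraries of code LH1 apart, which points to a structure of the samples, and within 1 code 734 and 441 genes changed in naive and resistant cells. In Braf cells and labelled RNA they exchanged treated libraries of the 2 lines. The line difference can enter any difference of responses, so its share leaves chance open. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real count and the highest other were 864 over 1 for resistance (Braf tumors), 2283 over 95 for interferon in Braf cells (naive) and 615 over 1 for transfer in CD45+ cells (resistant). For the rest the highest other was 0, against real counts of 4969, 4669, 2112, 1154, 2249, 5539 and 1935 for resistance (Braf cells, CT26 cells, CT26 tumors, CD45+ cells, sorted tumor cells, Rag2-/- mice and labelled RNA), 2577, 51 and 2161 for naive material on drug (Braf/Pten tumors, Braf tumors and CT26 tumors), 2798 for NSG-derived cells, 1128 for interferon in Braf cells (resistant), 968 and 559 for interferon in CT26 cells (naive and resistant), 229 for transfer in CD45+ cells (naive), 121 and 97 for transfer in tumor cells (naive and resistant), 3946 and 4716 for trametinib in Rag2-/- mice (naive and resistant) and 275 and 744 for MEK inhibition in labelled RNA (naive and resistant).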

How the results depend on the processing

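The fits without T cell libraries 7 and 9, those of labelled RNA scaled by converted reads and the coding of replicate blocks were chosen only after the result was seen.

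Every one of 40 counts stayed within 1.5 times under RLE normalization, as did 32 with DESeq2, 31 without a filter and 27 from the compared groups alone. Counts that moved more are given here. With DESeq2 there were 1304 for resistance (Braf tumors), 324 for naive material on drug (Braf tumors), 246 for interferon in Braf/Pten cells (difference), 453 and 118 for transfer in CD45+ cells (naive and difference) and 188, 192 and 12 for transfer in tumor cells (naive, resistant and difference). Without a filter there were 2774 for resistance (T cells), 113 for naive material on drug (Braf tumors), 482 for interferon in Braf cells (difference), 423 for interferon in CT26 cells (difference), 466 and 159 for transfer in CD45+ cells (naive and difference) and 193, 182 and 6 for transfer in tumor cells (naive, resistant and difference). With the compared groups alone there were 2276 and 3464 for resistance (CD45+ cells and sorted tumor cells), 4484 and 0 for naive material on drug (Braf/Pten tumors and Braf tumors), 701 for interferon in Braf/Pten cells (naive), 1237 and 1759 for interferon in Braf cells (naive and resistant), 1879 and 181 for transfer in CD45+ cells (naive and difference), 313, 53 and 1 for transfer in tumor cells (naive, resistant and difference) and 455 for MEK inhibition in labelled RNA (naive). Within 1 title code there were 734 and 35 for interferon in Braf/Pten cells (naive and difference). With 1 technical library per mouse there were 2447 and 1085 for trametinib in Rag2-/- mice (naive and difference). With all reads of SLAM-seq there were 6094 for resistance (labelled RNA) and 127, 1410 and 2439 for MEK inhibition in labelled RNA (naive, resistant and difference). The cause was not tested, except that all reads and single technical libraries differ by construction in the number of reads, and fits of fewer groups in the libraries that set the spread.

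Camera with an estimated correlation called 61 of 476 list tests, against 229 at the preset one, and the preset calls are therefore the less firm. Counts with replicate numbers as a block (1850, 232, 663 and 209) stayed within 1.5 times, as did labelled RNA scaled by converted reads, Braf/Pten cells without a batch term, dendritic cells without shallow libraries and T cells without libraries 7 and 9.

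With 1 library left out, the lowest and highest counts were 1152 to 4218, 338 to 989, 1033 to 1992, 527 to 780 and 1328 to 1972 for resistance (Braf/Pten tumors, Braf tumors, CT26 tumors, CD45+ cells and sorted tumor cells), 686 to 1707, 0 to 212 and 1024 to 2338 for naive material on drug (Braf/Pten tumors, Braf tumors and CT26 tumors), 508 to 1790, 372 to 1001 and 45 to 180 for interferon in Braf/Pten cells (naive, resistant and difference), 1442 to 2961 and 151 to 753 for interferon in Braf cells (naive and difference), 87 to 152, 363 to 572 and 6 to 37 for transfer in CD45+ cells (naive, resistant and difference), 56 to 86, 53 to 158 and 0 to 3 for transfer in tumor cells (naive, resistant and difference), 1429 to 2213 for trametinib in Rag2-/- mice (difference) and 154 to 197, 448 to 798 and 155 to 396 for MEK inhibition in labelled RNA (naive, resistant and difference). In the other results every such fit stayed within 1.5 times. A group left with 2 libraries was assumed to vary like the others.

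Of the named genes 1 reversed, Csf1 with a MEK inhibitor in resistant cells, at 0.0727 in all reads, which by construction count older RNA too. Of 1390 values of named genes with 1 library left out, 77 lost their call and none reversed. Of these, 42 were in whole tumors. Fits of the compared groups alone ended 8 calls and made 1, DESeq2 ended 3 and made 2, and no filter made 2. All reads ended 1 (Ccnd1 in the difference of MEK inhibition, 0.196) and scaling by converted reads 1 (Csf1 in resistant cells, -0.53). In simulated CD45+ counts 4 to 15 percent of 2-fold changes were called, against 74 to 90 percent in CT26 cells, which differ in depth and in spread, and a gene without a read is bounded only at 3 counts over the group.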

Other observations

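The Y-linked test was chosen only after the result was seen. Resistant Braf/Pten cells had almost no reads of the Y-linked genes Kdm5d, Ddx3y and Uty. In vitro Kdm5d was at 0.0299 ± 0.0345 CPM (SD, n = 6) in resistant and 20.7 ± 17.9 CPM (SD, n = 6) in naive cells. Sorted resistant tumor cells had Ddx3y at 0.117 ± 0.203 CPM against 56 ± 15.3 CPM in naive ones, and in Rag2-/- mice at 0.592 ± 0.166 CPM against 48.5 ± 11.3 CPM (SD, n = 3 each). Whole tumors, which hold cells of the host, were at 38.1 ± 22.9 and 40.4 ± 4.93 CPM (SD, n = 4 and 3).

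The highest level of the 3 genes in resistant cells was 0.3 percent of that in naive cells under the same title code. This restates the pattern, so loss of the Y chromosome from the resistant line cannot be told apart from silencing of the genes. The genes were lower in naive libraries of code LH2 than LH1 (Kdm5d 4.43 and 37.1 CPM).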
